A study of Mus musculus with 3 samples.

How the data were processed

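Total RNA of laser-microdissected ADM (acinar-to-ductal metaplasia), ductal and acinar cells was hybridised to 3 Agilent 1-colour mouse arrays, 1 per group. Per the labels' protocols, the RNA was purified on RNeasy Micro columns, 1.181 ng was amplified with the Ovation Pico WTA system, and 2.0 µg of the cDNA was labelled with Cy3. The 3 mice of the study were wild type and had caerulein pancreatitis 48 h earlier. Whether an array holds RNA of 1 mouse or a pool is not given in the sources used here. All 3 arrays were on 1 slide and were scanned on the same day, so slide and scan day do not separate the groups.

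The deposited scanner tables hold spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction 11.5.1.1 subtracted background, removed the spatial trend within each array and wrote the processed signal, with no scaling between arrays. The other deposited columns used were the median intensity of each spot and of its local background, and flags of 0 or 1 for saturation, outlier spots and signal well above background. The deposited value table of the series holds log2 values of 32939 probes. Set against the scanner values, its columns differed from the log2 processed signal by 1 constant per array, −6.17 for ADM, −6.58 for duct and −5.13 for acinar, to within 0.001 in 32637, 32649 and 32634 probes. That table was therefore neither centred per gene nor turned in sign, and its medians were −0.56, −0.63 and −0.57. The filter that chose its probes is not given in the sources used here.

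Each array had 62976 spots, of which 3671 were controls. Controls and spots with an outlier flag (117 on the ADM array, 110 on duct, 115 on acinar) were left out, which removed 17 probes. Spots of a probe were averaged as log2 processed signal, and the 75th percentile over the 55664 probes was subtracted from each array. Levels are log2 values on this scale, where 0 is the array's 75th percentile. This percentile was taken over all probes as planned, although under 50% of probes were well above background on the ADM and acinar arrays, and the percentile over probes well above background on all 3 arrays was an alternative.

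Probes were named through the RefSeq accession in the file, without its version, and a RefSeq gene table of the mouse assembly GRCm38.p6. The probes were annotated on build mm9, so the table served for names only. Of the probes, 28020 matched 1 symbol, 0 matched several and 27644 stayed unnamed here, which gave 21150 genes. Where a gene had more than 1 probe (5679 genes), the probe with the highest mean over the 3 arrays stood for it. The second-brightest probe served as a check. Among list and named genes, the probes of Adgre1, Csf1r, Ddx58, Dsp, Mbp, Ncbp2, Plvap, Tpi1 and Wfdc2 opposed each other by at least 2-fold in 1 or more comparisons, so the directions of these genes are open. Absence from this list does not settle the direction of a gene, since milder disagreement between probes was not listed. Trypsins, amylases, elastases, kallikreins and Reg genes are closely related families whose probes can bind more than 1 member.

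Differences are first array minus second in log2 units. A gene was compared where its probe was well above background on at least 1 of the 2 arrays. Where a side was not well above background, it was set to the higher of its own signal and the lowest signal well above background on that array, and the difference is a bound, written as "at least". A bound on the wrong side of 0 was set to 0. Genes were counted at a 2-fold difference. With 1 array per group no test between groups was possible, and none was planned.

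The 34 gene lists (638 genes, 628 of them on the array, 8 symbols updated) were fixed from textbook knowledge before the data were examined, as were the groups, the settings, the alternatives and the rule for named genes. Some list members that this rule would name are not reported here, although they stay in the list medians and counts. Each list of at least 3 compared genes is described by its median difference, the number of genes higher, lower or within 2-fold, and the percentile of its median among 10000 random lists of the same size drawn from 20 bins of mean expression. Percentiles describe these arrays and are not p-values. Some lists would lie outside the central 95% with no difference (the simulation below gives a count for lists of independent genes), and more can where the members of a list vary together. Candidates for naming were the 10 largest differences in each direction among genes well above background on both arrays. Only genes that kept direction and 2-fold under every background and scaling alternative were ranked. Added to them were the 5 brightest genes in each direction that were well above background on 1 array only. The 10 genes with the largest smaller difference for ADM against both others were taken as well. The text names part of these candidates. From each list up to 6 members a comparison are named, those with the largest differences or against the list's majority by at least 2-fold. Ptf1a, Krt19, Sox9, Amy2a5, Cpa1 and Spp1 are named throughout, and clone and model names were passed over. The position of ADM between acinar (0) and duct (1) was taken on the log2 scale over genes at least 4-fold apart between those arrays.

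Alternatives, changed singly, were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), median scaling, the 75th percentile of probes well above background on all arrays, quantile normalization, the deposited value table, only probes well above background on all 3 arrays, no filter on dim probes, the mean of a gene's probes, a 4-fold threshold, genes 8-fold apart for the position, and the linear scale for the position. Normexp was planned on the mean spot signal, a column not used here, and ran on the median spot and median background signals. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

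The steps were tested on simulated data made from the duct and acinar arrays (13766 genes, noise SD 0.15). All 100 genes made 4-fold different and all 100 made 8-fold different were counted in the true direction, and 0 of 13336 unchanged genes were counted. A 30-gene list raised by 1 log2 unit had a median of 1.02 and percentile 100. Of unchanged lists, 11 of a first 100 and 61 of a further 1000 lay outside the central 95%. A true position of 0.3 came out as 0.305 over 177 genes, and 0 of 2571 bounds overstated the simulated difference by more than 0.01 log2 units. That last result was fixed in advance, because the simulation called a gene dim by the same lowest signal that set its bound. It says nothing of bounds under the scanner's own flag. That noise was set near the spread between spots (median SD 0.106 on ADM, 0.0881 on duct and 0.122 on acinar). The test therefore says nothing of variation between animals, amplifications or probes of a gene.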

Results

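Gene expression was compared among acinar cells, duct cells and ADM cells of the mouse pancreas 48 h after caerulein pancreatitis. Caerulein is a cholecystokinin analogue that overstimulates acinar cells, and ADM is the conversion in which acinar cells lose secretory features and gain duct-like ones. The cells were cut by laser microdissection from frozen specimens of 3 wild-type mice, and how they were recognised is not given in the sources used here. Each cell type had 1 array, so no difference between groups has a replicate check, and the number of arrays limits the precision of every value. The study's purpose, per its title and design, was to set the profile of ADM cells beside those of duct and acinar cells in pancreatitis.

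The signal was similar on the ADM and duct arrays and weaker on the acinar array. Probes well above background numbered 27676 (49.7% of 55664) for ADM, 27849 for duct and 22654 (40.7%) for acinar, and the 75th-percentile signal was 72.2, 95.7 and 35.2 intensity units. No spot was saturated. Digestive enzymes held 14.7% of the signal of named genes on the acinar array, 6.49% on ADM and 1.22% on duct. That total includes the bright probes outside the lists described at the end, whose signal may not come from the named genes. Repeated spots of a probe had a median SD of 0.106, 0.0881 and 0.122 log2 units, which covers spotting and scanning only. Different probes of a gene matched far less well. Across genes with a second probe, the differences given by the 2 probes correlated at r = 0.384 for duct against acinar (1833 genes), 0.365 for ADM against acinar (1906) and 0.279 for ADM against duct (2295). Of those at least 2-fold apart, the second probe had the same direction in 608 of 886 (68.6%), 481 of 694 (69.3%) and 600 of 896 (67.0%). Values of single genes thus rest on 1 probe each.

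The acinar and duct arrays differed first in digestive enzymes. Of 24 enzyme genes, 0 were higher in duct, 23 were at least 2-fold lower and 1 (Dnase1, 0.57, named after its value was seen) lay within 2-fold. The median difference was −5.61 log2 units (49.0-fold), below all 10000 matched random lists. The lipase relative Pnliprp2 was 550-fold lower in duct, the elastases Cela1 and Cela2a 346-fold and 297-fold, and the kallikrein Klk1 162-fold. Cpa1, a carboxypeptidase, was 28.8-fold lower (7.05 against 11.90) and the amylase Amy2a5 differed by −3.33 (8.75 against 12.07), so both were still bright on the duct array. Genes of zymogen granules and secretion followed the enzymes, with 16 of 17 lower, 1 higher (the secretory GTPase Rab27b, 1.31) and a median of −5.67, below all random lists. Among them the granule protein Cuzd1 was at least 1275-fold lower in duct, the cholecystokinin receptor Cckar at least 447-fold and the aquaporin Aqp12 at least 379-fold.

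Acinar transcription factors were lower in duct in 8 of 12 genes and higher in 0, with a median of −3.16, below all random lists. Rbpjl, a subunit of the acinar PTF1 complex, was 183-fold lower, Ptf1a, the DNA-binding subunit of that complex, 17.2-fold lower, the nuclear receptor Nr5a2 differed by −5.29 and Gata4 by at least −6.90. Ductal markers went the other way, with 20 of 33 higher in duct, 4 lower and 9 within 2-fold, a median of 1.75 and a percentile of 100. The carbonic anhydrase Car2 was at least 5.65 log2 units higher, the water channel Aqp1 5.20, and the bicarbonate transporter Slc4a4 4.87. Krt19 was 4.12-fold higher, Sox9 3.24-fold and Spp1 2.61-fold. Kcnj15 (at least −3.48), the trefoil gene Tff2 (−3.22) and Cldn10 (−2.66) were among the 4 members lower in duct.

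**Figure D1:**
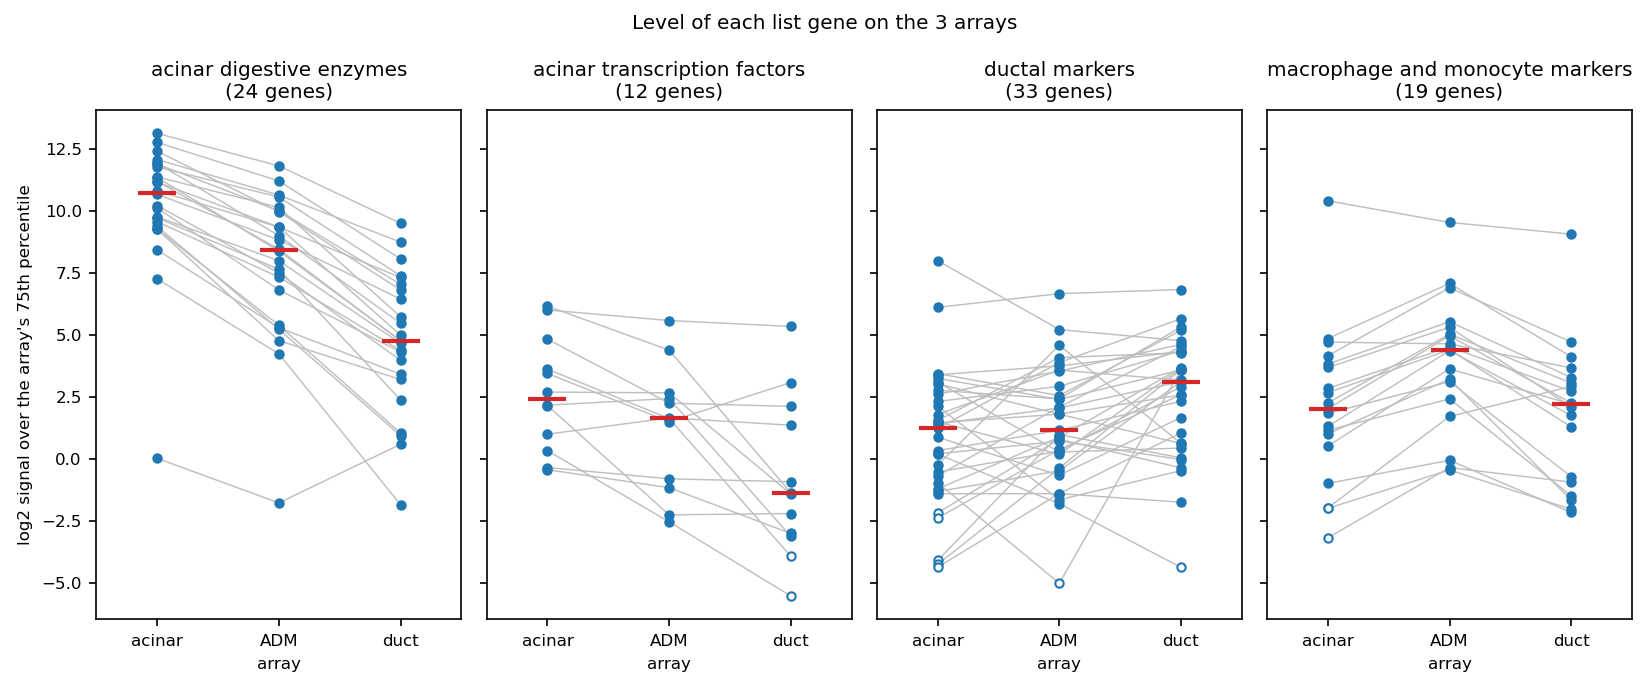
Level of each gene of 4 lists on the acinar, ADM and duct arrays (y axis, log2 signal over the array's 75th percentile; grey lines join a gene, filled points are well above background, open points are not, red bars are medians; 1 array per group). Enzyme genes such as Cpa1 step down from 11.90 on the acinar array to 10.01 on ADM and 7.05 on duct, while most macrophage markers sit highest on ADM.

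Endoplasmic reticulum stress genes were lower in duct as well, in 20 of 25 and higher in 1 (Ddit3, at least 1.91), with a median of −2.01, below all random lists; Ero1b differed by −5.44, Sel1l, part of the degradation machinery, by −5.12 and the chaperone cofactor Sdf2l1 by −4.74. Genes of amino acid handling and protein synthesis were lower in 15 of 18 and higher in 0 (median −2.16, below all random lists), among them Gatm, a creatine synthesis enzyme (−7.46), Gnmt (−6.99) and the serine synthesis enzyme Phgdh (−6.09). Cell-cycle genes were lower in 17 of 27 and higher in 0, with a median of −2.15, below all random lists, and included Rrm1 (−5.11), the proliferation marker Mki67 (−5.00), Ccna2 (at least −4.94) and Birc5 (−4.88). Regenerating and acute-phase genes divided, with 4 higher, 7 lower and 4 within 2-fold (median −0.89, percentile 4.76). The Reg genes Reg3a (−6.83), Reg3d (−6.49) and Reg3g (−6.24) were lower in duct, and the acute-phase genes Lcn2 (4.07), Lbp (at least 3.33) and C3 (2.97) were higher. Adipocyte markers were lower in 5 of 6 genes (median −2.06, percentile 0.69), including Lpl (−3.58), a call lost with the filter on all 3 arrays and with no filter (highest percentile 10.8).

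Interferon-stimulated genes were higher in duct in 14 of 21 and lower in 0 (median 2.02, percentile 99.97), with Irf7 at least 5.70 higher, Ifit3 4.95, Oasl2 4.19 and Irf1 4.08. Epithelial junction genes were higher in 9 of 18 and lower in 2 (median 1.08, percentile 99.3), with Tjp1 at 2.83 and Epcam at 2.73. Pancreatic progenitor genes were higher in 9 of 18 and lower in 5 (median 1.18, percentile 99.5, but inside the central 95% with the mean of probes), where the Notch target Hes1 (4.20) and Sox4 (3.94) were higher and Foxa3 (at least −6.53) lower. Targets of the Hippo effector YAP were higher in 7 of 14 and lower in 2 (median 1.28, percentile 98.8), led by Ccn2 (at least 83.1-fold higher), with Birc5 lower, and normexp and the filter on all 3 arrays put that list inside the central 95%. Epithelial-mesenchymal transition genes were higher in 11 of 16 and lower in 1 (Lox, well above background in acinar only), with a median of 1.91 and a percentile of 99.98. Markers of other cell types moved with these groups. Fibroblast and stellate cell markers, which share Mmp2, Sparc and Vim with the transition list, were higher in duct in 15 of 21 (median 1.71, percentile 99.98), with Thy1 at least 146-fold higher and Col5a1 at 5.37. Endothelial markers were higher in 7 of 12 (1.92, percentile 99.98, but inside with the filter on all 3 arrays), with Vwf at least 4.40, and nerve and Schwann cell markers in 4 of 5 (1.70, percentile 99.3, but inside with normexp and the mean of probes), with S100b at least 3.34.

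Outside the lists, genes were ranked where they were well above background on both arrays and kept 2-fold under the background and scaling alternatives. The largest differences among them were Glp1r, the incretin receptor (761-fold), Chst2 (238-fold) and Ahcy (173-fold), all lower in duct. Higher in duct were Myadm (131-fold), Kif12 (111-fold), Slbp (88.4-fold) and the calcium-binding protein S100a6 (74.1-fold). Gpr153 was at least 153-fold higher in duct, and Cabp2 at least 936-fold higher in acinar. In all, 3791 of 13826 genes were at least 2-fold higher in duct and 3398 at least 2-fold higher in acinar, and the levels correlated at r = 0.758 across 9539 genes, which are not independent replicates. Duct held 52.7% of these genes and 64.7% with median scaling. That scaling moved the differences of genes well above background on both arrays by 0.39 and the median of all genes by 0.28. A bound set to 0 need not move with it. Normexp background correction gave 1501 genes at least 2-fold higher in acinar than in duct.

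In ADM the same acinar groups were lower than in acinar cells, by less. Every one of the 24 enzyme genes was at least 2-fold lower in ADM, with a median of −2.15 (4.44-fold), below all random lists. Pla2g1b, a phospholipase, differed by −4.48, Cela1 by −4.14 and Cela2a by −3.87, while Cpa1 was 3.69-fold lower (10.01 against 11.90) and Amy2a5 2.69-fold lower (10.64 against 12.07). Granule and secretory genes were lower in 15 of 17 and higher in 0 (median −2.18, below all random lists), with Aqp12 at −4.33, Zg16 at −3.47 and Tmed6 at −3.45. Acinar transcription factors divided into 6 lower and 6 within 2-fold, with a median of −1.25 and a percentile of 0.18. Nr0b2 (−4.41), Mecom (−2.87) and Bhlha15 (−2.58), the secretory factor also called Mist1, were lower, and Ptf1a differed by only −0.03 (2.67 against 2.70). With only probes well above background on all 3 arrays, or with the mean of a gene's probes, this list's median lay inside the central 95%.

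Ductal markers in ADM were mixed. Of 33, 10 were higher than in acinar, 8 lower and 15 within 2-fold, with a median of 0.61 and a percentile of 99.2. The claudin Cldn4 was 28.3-fold higher, Anxa3 at least 3.04 log2 units, and Krt7, a duct keratin, at least 2.85, whereas Onecut1 (−3.77) and Cldn10 (−2.82) were lower. Spp1 was 3.46-fold higher, and Krt19 (0.61) and Sox9 (0.64) were within 2-fold. Metaplasia regulators were higher in 10 of 24 and lower in 3 (median 0.60, percentile 98.2), a call lost with the filter on all 3 arrays and with the mean of a gene's probes (lowest percentile 95.03). In that list Mmp7, a protease of duct-like metaplasia, was at least 5.22 log2 units higher, the cell-cycle inhibitor Cdkn1a at least 3.69 and the transcriptional coactivator Wwtr1 at least 2.79. Agr2 was lower, with a difference of at least −3.57. Gastric and mucous metaplasia genes were higher in 3 of 17 and lower in 8 (median −0.42, percentile 12.9), with Tff2 at −2.78.

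Macrophage and monocyte markers were higher in ADM than in acinar in 16 of 19 genes and lower in 0, with a median of 1.70 (3.26-fold), above all random lists. Cd14, a lipopolysaccharide receptor, was at least 3.68 log2 units higher, Ms4a7 3.05, the immune receptor chain Fcer1g 2.94, the complement gene C1qc 2.78 and the protease Ctss 2.74. Fibroblast and stellate cell markers were higher in 15 of 20 and lower in 1, the contractile gene Acta2 (−3.63), with a median of 1.80, above all random lists. Thy1 was at least 4.86 log2 units higher, Col5a1 5.53 and Postn 3.86. Beside these, epithelial-mesenchymal transition genes were higher in 13 of 15 and lower in 0 (median 2.19, percentile 100), with S100a4 at least 5.24 and Tgfbi at least 4.83. NF-kB targets and chemokines were higher in 11 of 20 and lower in 0 (median 1.13, percentile 99.9, but inside the central 95% with the filter on all 3 arrays), with Cxcl5 at least 4.12 and the adhesion receptor Vcam1 4.05. Interferon-stimulated genes were higher in 14 of 20 and lower in 1, Oas2 (−2.48), with a median of 1.52 and a percentile of 99.98; Rsad2 was at least 4.39 higher and Irf1 2.92. Immediate-early genes were higher in 7 of 19 and lower in 1 (median 0.66, percentile 97.8, but inside with normexp and with no filter), with Klf2 at 4.09 and Atf3 at 2.90. Endothelial markers were higher in 5 of 10 and lower in 2 (1.01, percentile 98.04, but inside under 3 alternatives, down to 85.2), and islet markers were higher in 6 of 18 and lower in 1 (0.48, percentile 97.97, but inside with the mean of probes).

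Endoplasmic reticulum stress genes were lower in ADM than in acinar in 14 of 25 and higher in 1 (median −1.33, below all random lists), with Hyou1 at −3.69 and Ero1b at −3.53. Regenerating and acute-phase genes were lower in 7 of 14 and higher in 4 (median −1.04, percentile 0.07). Reg3g (−2.95) was lower, and Lcn2, which encodes an iron-carrier-binding protein, was 26.2-fold higher and the haemoglobin-binding protein Hp 3.34 log2 units higher. Amino acid genes were lower in 8 of 18 and higher in 2, Shmt2 (2.02) and Cth (1.47), with a median of −0.91 and a percentile of 0.20. Cell-cycle genes were lower in 13 of 30 and higher in 3 (median −0.37, percentile 5.73), with Ccna2 at least −4.81, Ube2c −3.07 and Cenpa at least 3.31. EGFR ligands and receptors were higher in 4 of 8 and lower in 2 (median 1.07, percentile 97.6), with Erbb3 at 4.08 and Egf at least −4.03, and 5 of the 8 alternatives put that list inside the central 95%.

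Myadm was 83.6-fold higher in ADM than in acinar, the chemokines Ccl9 and Ccl6 45.7-fold and 28.4-fold, and the matrix gene Thbs4 45.4-fold. Cygb was at least 89.5-fold higher. Higher in acinar were the kinase Map3k13 (117-fold), Tia1 (95.2-fold), Ptpn21 (64.4-fold), Tet3 (58.1-fold), Glp1r (44.5-fold) and, well above background in acinar only, the vesicular transporter Slc18a1 (at least 126-fold). In all, 2966 of 13632 genes were at least 2-fold higher in ADM and 2999 at least 2-fold higher in acinar, with r = 0.854 across genes. ADM held 49.7% of these genes and 58.9% with median scaling. That scaling moved the differences of genes well above background on both arrays by 0.23 and the median of all genes by 0.05. Normexp background correction gave 1707 genes at least 2-fold higher in ADM than in acinar and 942 genes at least 2-fold higher in acinar than in ADM.

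Against duct cells, ADM had far higher levels of digestive enzyme and granule transcripts. Of the 24 enzyme genes 23 were at least 2-fold higher in ADM and 1, Dnase1 (−2.36), was lower, with a median of 3.16 (8.95-fold), above all random lists. Pnliprp2 was 67.6-fold higher, Klk1 differed by 5.27 and Prss2, a trypsinogen, by 4.41, with Cpa1 7.79-fold and Amy2a5 3.72-fold higher. Granule and secretory genes were higher in 15 of 17 and lower in 0 (median 3.45, above all random lists), with Cuzd1 and Cckar both at least 237-fold higher. Acinar transcription factors were higher in 5 of 12 and lower in 1 (Creb3l1, −1.58), with a median of 0.52 and a percentile of 92.8. Rbpjl was 53.6-fold higher, Nr5a2 47.0-fold, Gata4 at least 4.91 log2 units and Ptf1a 16.8-fold. Regenerating and acute-phase genes were higher in 7 of 14 and lower in 2 (1.96, percentile 100, but inside the central 95% with no filter), with Reg3a at 5.28, Reg3b at 4.74 and Hp at 4.05. Amino acid genes were higher in 13 of 18 and lower in 0 (2.29, above all random lists), with Gatm at 5.44 and Phgdh at 5.09. Endoplasmic reticulum stress genes were higher in 10 of 25 and lower in 2 (0.66, percentile 99.9), with Sel1l at 3.69. Cell-cycle genes were higher in 14 of 27 and lower in 0 (1.06, percentile 99.99), with Rrm1 at 5.12, Mki67 at 3.67 and Cenpa at least 4.54.

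Ductal markers were lower in ADM than in duct in 19 of 33, higher in 4 and within 2-fold in 10, with a median of −1.17 and a percentile of 0.02. Tspan8 was at least 107-fold lower in ADM, Car2 differed by −3.96 and Onecut2 by −3.46. Krt19 was 2.69-fold lower and Sox9 2.08-fold lower, Spp1 was within 2-fold (0.41), and Cldn4 went the other way by 3.95. Pancreatic progenitor genes were lower in 10 of 18 and higher in 2 (median −1.12, percentile 0.18), with Foxa1 at least −4.57, Pdx1, the pancreatic master regulator, −2.82, and Foxa3 at least 4.88. Cilium genes were lower in 15 of 30 and higher in 9 (−0.90, percentile 0.53, but inside the central 95% with normexp and the mean of probes), with Foxj1, a driver of motile cilia, at least −4.95 and Nek8 −4.89. Interferon-stimulated genes were lower in 14 of 21 and higher in 3 (−1.47, percentile 0.09), with Irf7 at −3.73 against Rsad2 at 4.82. Nerve and Schwann cell markers were lower in 4 of 5 (−2.49, percentile 0.23), mesothelial markers in 2 of 3 (−3.49, percentile 1.15, all 3 of them bounds, and turned in sign with no filter), and endothelial markers in 7 of 13 (−1.11, percentile 2.78, inside the central 95%).

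Macrophage and monocyte markers were higher in ADM than in duct in 15 of 19 genes and lower in 1, Cd14 (−1.21), with a median of 2.18 (4.54-fold), above all random lists. The lysozyme gene Lyz2 differed by 4.87, Fcgr3 by 3.90, the complement gene C1qa by 3.83 and Cd68 by 3.21. Beside them, NF-kB targets and chemokines were higher in 9 of 22 and lower in 4 (median 0.53, percentile 95.4), with Vcam1 at 3.88. Fibroblast and stellate cell markers did not separate ADM from duct, with 4 of 21 higher, 6 lower, a median of 0.05 that median scaling turns negative and a percentile of 56.5. Postn was at least 5.31 log2 units higher in ADM and Acta2 differed by −3.87. Epithelial-mesenchymal transition genes were also level, with 5 of 17 higher and 3 lower (0.20, percentile 74.0).

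Higher in ADM outside the lists were Ahcy (75.9-fold), the transcription factor Ets1 (66.7-fold), Wars (61.5-fold), Bex2 (at least 263-fold) and Emilin2 (at least 132-fold). Higher in duct were the kinase Taok2 (146-fold), Rgs16 (84.8-fold), Spink4, a secreted protease inhibitor of mucous cells (78.0-fold), the orphan nuclear receptor Nr2f2 (47.8-fold) and Fcgbp (at least 162-fold). In all, 3121 of 14475 genes were at least 2-fold higher in ADM and 3594 at least 2-fold higher in duct, with r = 0.834 across genes. ADM held 46.5% of these genes and 40.7% with median scaling. That scaling moved the differences of genes well above background on both arrays, and the median of all genes, by −0.16. Normexp background correction gave 1503 genes at least 2-fold higher in ADM than in duct and 2176 genes at least 2-fold higher in duct than in ADM.

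**Figure D2:**
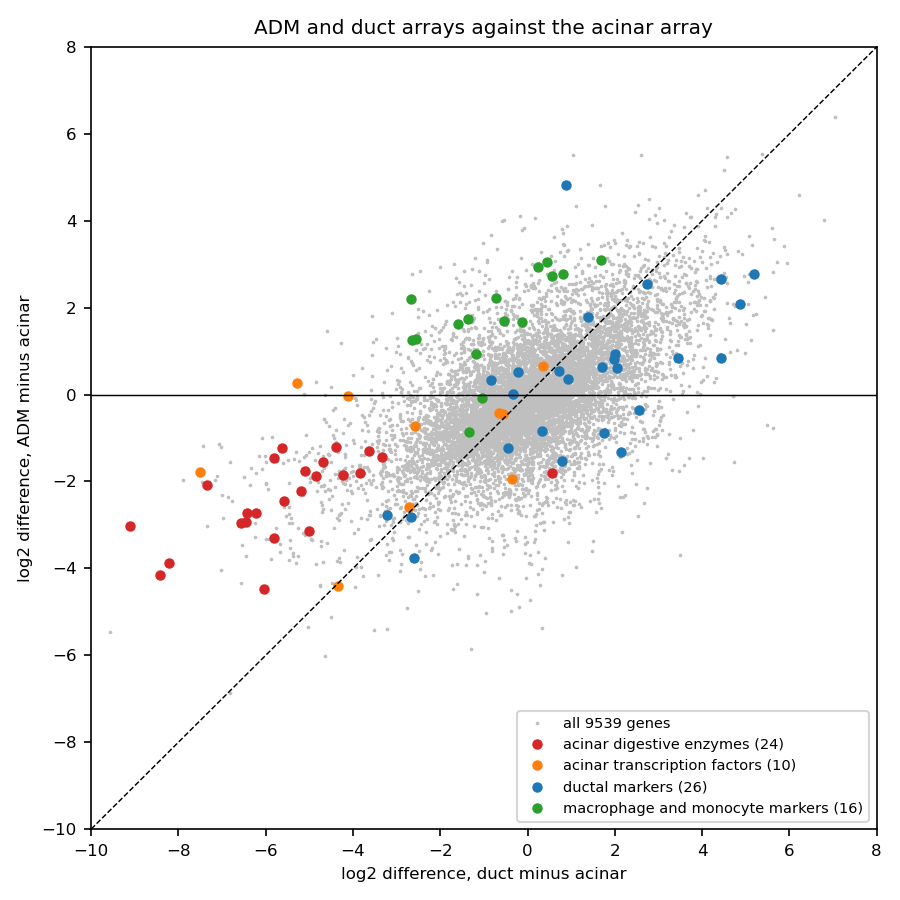
Log2 difference from the acinar array for each gene well above background on all 3 arrays (grey, 9539 genes), with duct minus acinar on the x axis and ADM minus acinar on the y axis; coloured points are genes of 4 lists and the dashed line marks equal differences. Enzyme genes (red) other than Dnase1 lie lower left, above the dashed line, and macrophage markers (green) lie mostly above 0 on the y axis.

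On genes that separated acinar from duct at least 4-fold, ADM had a median position between the 2. Its median position, from 0 at the acinar level to 1 at the duct level, was 0.484 (quartiles 0.167 and 0.784) over 3523 genes, and 72.9% of genes lay between. Enzymes had a median position of 0.430 (23 genes), granule genes 0.459 (16), acinar transcription factors 0.285 (8) and ductal markers 0.464 (19). Regenerating and acute-phase genes (0.294, 9 genes) and amino acid genes (0.270, 10) sat nearer acinar, and the 14 cell-cycle genes far enough apart had a median of 0.619, although over the whole list ADM differed less from acinar (−0.37) than from duct (1.06). Epithelial-mesenchymal transition genes stood at the duct level (1.03, 9 genes), and the median of the macrophage markers far enough apart to be placed lay beyond the acinar end (−0.491, 4 genes). The position depended on the scale: genes high in duct had 0.467 on the log2 scale and 0.215 on the linear one, and genes high in acinar 0.506 and 0.779. For comparison, 43.2% of 2343 genes placed duct between acinar and ADM (median position 0.775). In the same way, 66.1% of 3009 genes placed acinar between duct and ADM (median position 0.637). Genes picked for a large difference between 2 arrays tend to place the remaining array between them. A median between 0 and 1 therefore does not by itself show that ADM is intermediate.

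On the ADM array 1186 genes were at least 2-fold higher than on both other arrays and 1008 at least 2-fold lower than on both. The corresponding counts were 2212 and 1561 for duct and 1851 and 1735 for acinar. Among the genes highest in ADM were Gpnmb, a glycoprotein of activated macrophages (at least 40.3-fold over acinar and at least 94.5-fold over duct), the chemokine Ccl9 (45.7-fold and 22.3-fold), the neutrophil gene Retnlg (at least 22.4-fold and at least 52.7-fold) and the interferon-induced Rsad2 (at least 21.0-fold and 28.3-fold). Tepp, Dipk1b, Pwwp3a, Cldn23, Atpsckmt and Suds3 completed the 10 named by rule. Normexp background correction gave 511 genes at least 2-fold higher in ADM than in both others and 247 genes at least 2-fold lower in ADM than in both others.

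**Figure D3:**
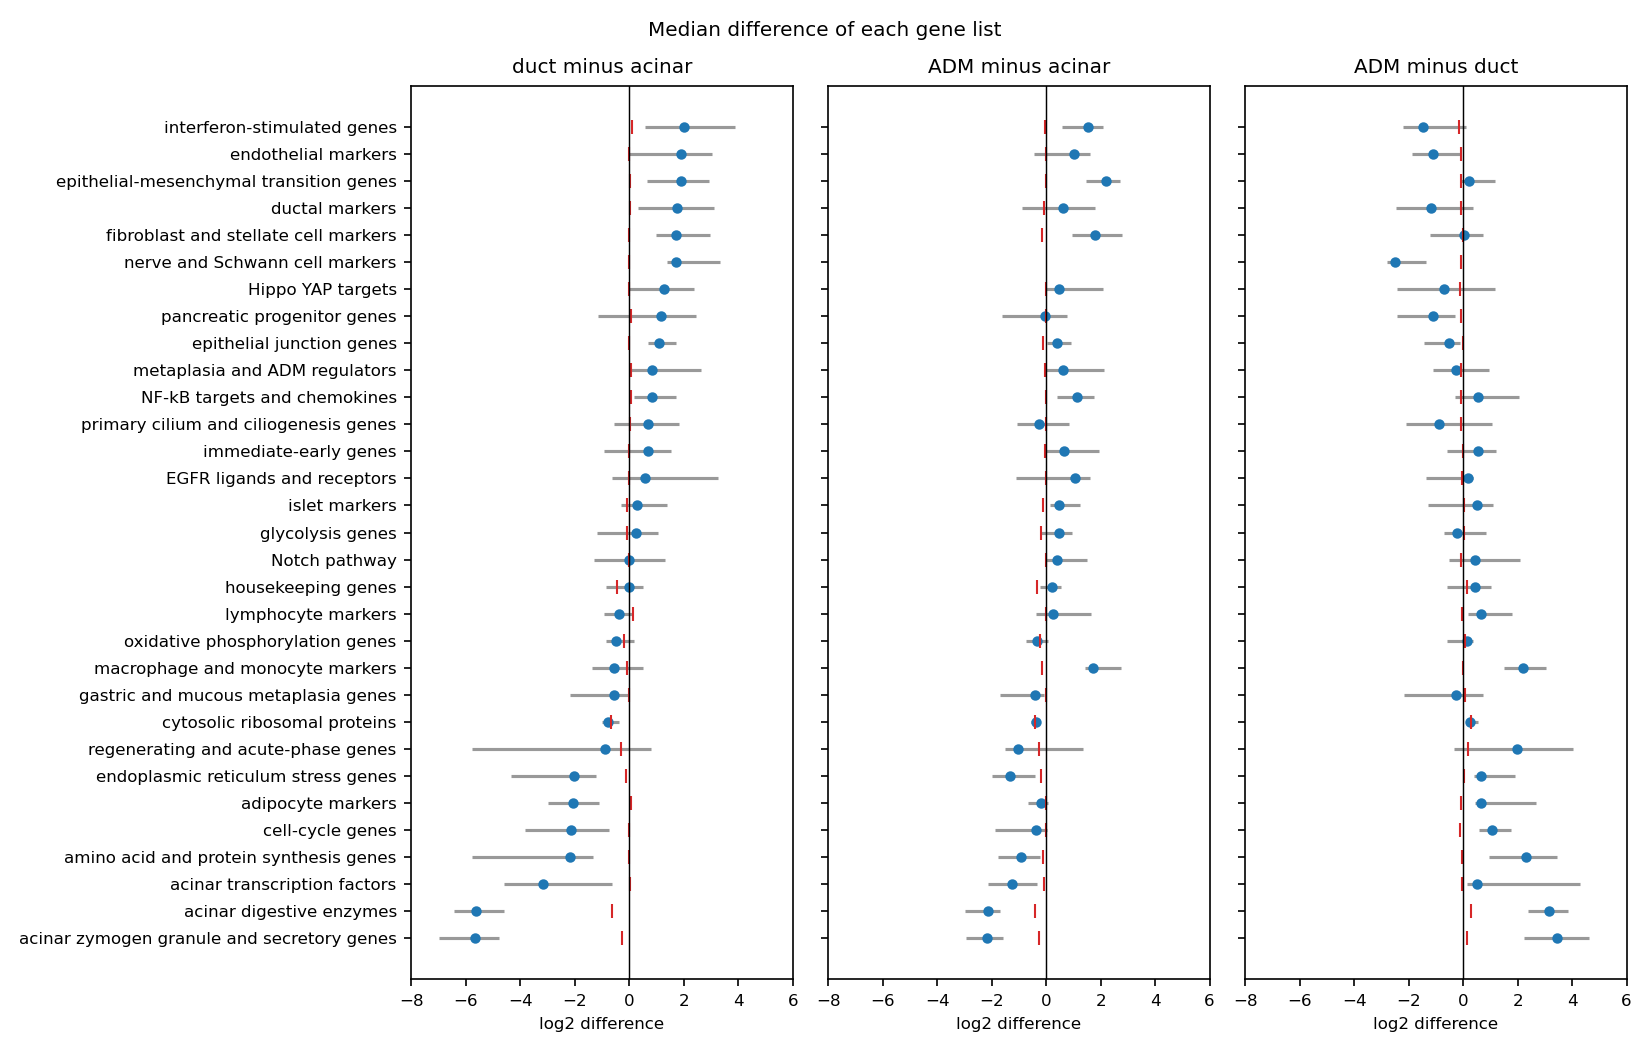
Median log2 difference of each gene list in the 3 comparisons (blue points; grey bars, quartiles over list members; red ticks, median of matched random lists), ordered by duct minus acinar. Enzymes stand at −5.61, −2.15 and 3.16 in duct minus acinar, ADM minus acinar and ADM minus duct, and macrophage markers at −0.54, 1.70 and 2.18.

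The remaining lists lay inside the central 95% wherever no other result is given. In duct against acinar, medians were 0.70 for cilium genes (10 of 28 higher, 6 lower, percentile 95.6), 0.85 for metaplasia regulators (10 of 22 higher, 3 lower, 95.8), 0.84 for NF-kB targets (8 of 17 higher, 1 lower, 91.9), 0.00 for the Notch pathway (7 of 17 higher, 5 lower, 45.2) and −0.54 for macrophage markers (3 of 19 higher, 8 lower, 10.6). Glycolysis genes had medians of 0.25, 0.48 and −0.22 in duct against acinar, ADM against acinar and ADM against duct, with percentiles of 85.1, 97.3 and 21.5 and with 5 of 16, 3 of 14 and 4 of 16 genes higher. Oxidative phosphorylation genes stood at −0.50, −0.33 and 0.15 (percentiles 14.0, 28.8 and 69.9; 1 of 25 higher in each, and 4, 3 and 1 lower). Cytosolic ribosomal proteins stood at −0.76, −0.39 and 0.24 (22.7, 60.7 and 35.2; 0, 0 and 1 of 29 higher), and housekeeping genes at −0.02, 0.21 and 0.45 (86.1, 96.7 and 89.4; 1, 2 and 4 of 13 higher). Lymphocyte markers had medians of −0.38, 0.24 and 0.66 (20.5, 82.3 and 92.6; 1 of 8, 5 of 11 and 5 of 12 higher). Neutrophil markers had too few compared genes in duct against acinar, and elsewhere stood at 0.00 and 0.85 (58.4 and 90.8; 2 and 3 of 6 higher), with S100a9 at least 3.44 higher in ADM than in acinar. Of the erythroid markers only 2 were compared, and Hba-a1 was 3.00 log2 units higher in ADM than in acinar and 4.69 higher than in duct. Median scaling can turn the sign of list medians that lie between 0 and −0.39 in duct against acinar, 0 and −0.23 in ADM against acinar, and 0 and 0.16 in ADM against duct. Lists outside the central 95% numbered 16 of 31 in duct against acinar, 17 of 31 in ADM against acinar and 13 of 33 in ADM against duct, and 11, 10 and 10 of them were outside under every alternative that gave a value. Those that at least 1 alternative put inside were, in duct against acinar, the progenitor, YAP, endothelial, adipocyte and nerve lists; in ADM against acinar, the acinar transcription factor, EGFR, metaplasia, immediate-early, NF-kB, endothelial and islet lists; and in ADM against duct, the cilium, regenerating and mesothelial lists.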

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

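Probes named only by a chromosome region carried signal, and they stand apart because no comparison of genes used them. Of 16188 such probes, 38.5% were well above background on the ADM array (6231 probes), 39.0% on the duct array (6314) and 31.1% on the acinar array (5033), and 4121 were well above background on all 3. Negative control spots, 308 on each array, were well above background in 0% of spots on ADM, 0.325% on duct and 0% on acinar. Which transcripts these probes detect is not given in the sources used here and was not tested, and no biological explanation was tested.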

How the results depend on the processing

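All alternatives named here were planned. With 1 array per group, leaving out an array was not possible. No paired analysis was possible because each group has 1 array and no test. Over the counts, positions and correlations, 82 of 106 alternative values stayed close to the reported ones (counts within 1.5 times) and 24 moved, and the median position of ADM between acinar (0) and duct (1) ran from 0.437 with normexp to 0.522 with no filter over all these genes together. Median scaling, quantile normalization and the mean of a gene's probes moved none of these counts that far. The percentile of probes well above background on all arrays did not either. The deposited value table also moved none, but it is no independent check. It holds the same processed signal less a constant per array, close to the log2 percentile signal subtracted here. For its probes, agreement with the reported values was thus largely fixed in advance. The totals of alternative values in this paragraph include it. For list medians over matched random lists, 672 of 755 values stayed within 1 SD of random lists, and 37 did not keep their sign, of which 2 belonged to lists outside the central 95%. A scaling constant moves a list and its random lists alike, apart from bounds. Median scaling (94 of 95 stayed) and the deposited value table (95 of 95) could hardly move these values. Nor could the percentile of probes well above background on all arrays (95 of 95). Normexp kept 66 of 95, the filter on all 3 arrays 69 of 90 and no filter 79 of 95. The mean of probes kept 82 of 95 and quantile normalization 92 of 95. For named genes, 641 of 939 stayed within the spread of spots and 298 moved, with normexp moving 118 of 124, and 4 did not keep their sign, all of them Ptf1a in ADM minus acinar (−0.03). The filter on all 3 arrays gave a value for 71 of those 124, since it leaves out bounds.

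Normexp, whose offset draws dim signals together, gave 1501 genes at least 2-fold higher in acinar than in duct, 1707 genes at least 2-fold higher in ADM than in acinar and 942 the other way, 1503 genes at least 2-fold higher in ADM than in duct and 2176 genes at least 2-fold higher in duct than in ADM, with 511 genes at least 2-fold higher in ADM than in both others and 247 genes at least 2-fold lower in ADM than in both others. Keeping only probes well above background on all 3 arrays, which tests fewer genes, gave 2298 genes at least 2-fold higher in duct than in acinar, and in the order ADM over acinar, ADM over duct, duct over ADM and ADM over both others 1688, 1717, 2055 and 533. Without a filter on dim probes, which adds genes below background on both arrays, 8829 genes were higher in acinar than in duct, 7969 genes at least 2-fold higher in acinar than in ADM and 2038 lower in ADM than in both others, and the correlation across genes, duct and acinar, was 0.808. A 4-fold threshold lowered the counts by construction, to 1924 for duct over acinar, 1599 for acinar over duct, 1243 for ADM over acinar, 1100 for acinar over ADM, 1422 for ADM over duct, 1587 for duct over ADM, and 379 and 295 for ADM above and below both others.

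Of the 755 alternative values of list medians over matched random lists, 81 moved and 2 reversed. Some of them follow, and the cause was not tested. Acinar transcription factors had −3.20 in duct minus acinar, against −1.89 with normexp, −2.55 with the filter on all 3 arrays and −2.51 with the mean of probes. In ADM minus acinar they had −1.16, against −0.73, −0.42 and −0.50 in that order, and in ADM minus duct 0.57, against 1.13 with no filter and 1.13 with the mean of probes. Ductal markers had 1.70 in duct minus acinar and 0.71 in ADM minus acinar, against 1.24 and 0.38 with normexp. Acinar digestive enzymes in ADM minus acinar had −1.74, against −1.91 with the mean of probes, and macrophage and monocyte markers in ADM minus duct 2.18, against 2.47 with the filter on all 3 arrays. Both lists outside the central 95% that turned sign did so with no filter on dim probes, EGFR ligands and receptors in ADM minus acinar from 1.07 to −0.57 and mesothelial markers in ADM minus duct from −3.44 to 0.14. Signal over background was lowest on the acinar array, so bounds against acinar are the loosest.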

Other observations

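The tests on array scaling, on the digestive enzymes and on bright list genes were chosen after their result was seen, and the tests on macrophage transcripts outside the lists and on the gaps between probes were written before theirs.

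Islet hormone transcripts were bright on all 3 arrays. Of 20 islet markers, 15 were well above background on every array, and the insulin gene Ins2 stood at 9.25 on ADM, 8.36 on duct and 8.80 on acinar, which ranked it 107, 131 and 175 among all genes. The glucagon gene Gcg stood at 5.98, 5.48 and 4.74, and the somatostatin gene Sst at 3.92, 4.90 and 3.81. These are markers of a cell type other than those dissected. Whether RNA of neighbouring cells reached all 3 arrays was not tested. The question also bears on the macrophage markers, on the enzymes still bright on the duct array and on the acinar transcripts of the ADM array. In the Notch pathway, ADM was higher than acinar in 7 of 18 genes and lower in 4 (median 0.41, percentile 92.9) and higher than duct in 7 and lower in 2 (0.45, percentile 92.0). The ligand Jag1 was 3.07 log2 units higher in ADM than in acinar, the target Hey1 at least 2.86 and the pathway's DNA-binding factor Rbpj 2.53, whereas Lfng, which modifies Notch receptors, was lower (−3.02). Hexokinases divided, with Hk1 higher than in acinar by 5.61 in duct and 3.83 in ADM, and Hk2 lower by −3.14 and −3.61. Among YAP targets, ADM minus duct had a median of −0.69 (inside the central 95% of random lists) with 4 of 14 genes higher and 7 lower, and Ptpn14 was 3.24 higher in ADM while Amotl2 differed by −3.69.

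Macrophage markers stood above both other arrays in ADM. Scaling of the ADM array was excluded as the whole cause, since over 18 values from both comparisons and all settings the list's median exceeded that of matched random lists by at least 1.73, against an SD of 0.289 between random lists. Macrophages or their RNA in the dissected ADM material were tested on macrophage transcripts outside all lists, and 5 of 8 (Laptm5, Lgmn, Apoe, Cd53 and Lcp1, but not Cybb, Spi1 and Plek) were at least 2-fold higher than on both other arrays, which does not decide. Of the list's 19 compared genes, 16 were also well above background on the acinar array. Macrophage RNA in the dissected material and expression of these genes by ADM cells themselves both stay open. More macrophages around ADM than around the other cells stay open as well. The chemokine, interferon, fibroblast and epithelial-mesenchymal transition lists that were higher in ADM than in acinar carry the same question. So do the fibroblast, transition, endothelial and nerve lists that were higher in duct than in acinar.

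Digestive enzymes lay between acinar and duct in ADM, but unevenly. A mix of acinar and duct RNA alone was fitted to the enzymes. At the best share (15.8% acinar) they kept a residual SD of 0.968 log2 units, against 0.943 with no fit. With no mix fitted, the SD was 0.263 for ribosomal protein genes and 0.640 for 71 genes as bright. It was 1.33 for all genes well above background on both arrays. Noise between amplifications was not measured, so these values do not decide against a mix. Enzymes brighter on the acinar array differed less in ADM (rho = 0.550 across 24 genes), as signal compression at the brightest probes would give. Without the dimmest enzyme, Dnase1, rho was 0.645. After a linear fit on the acinar signal the SD was 0.921 (0.943 before it), and without Dnase1 0.765 (0.955 before it). A linear effect of brightness thus left most of the spread, of which the part due to amplification is unknown. Of 6 enzymes with an acinar level between 9 and 10, the difference in ADM ran from −1.77 for Prss1 to −4.48 for Pla2g1b. Gene-specific loss of enzyme RNA in ADM cells may underlie this, as a hypothesis found and examined on the same arrays, and differences in amplification of single transcripts and binding of related family members were not tested.

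Probes of 43 genes outside the lists were as bright as digestive enzymes on every array, at a level of at least 9.74, among them Sp110, Ubtf, Creb5, Pak4 and the ribosomal protein gene Rpl41, named after their values were seen. In the 27 of these with another probe, the bright probe exceeded the next by a median of 12.5 log2 units, against 2.19 over 123 list genes, and 0 of 27 had another probe within 1 log2 unit (smallest gap 7.97). Because picking bright probes could widen such gaps, list genes that reached 9.74 on at least 1 array were set beside them: of 5 with another probe, Amy2a5, Cela3a, Clps and Prss1 had gaps of 1.80 to 2.76 and Itgam 10.87. The gap of Itgam lies among those of the 27. Itgam, which is also in the macrophage list, is not a clean control, because its probe was itself bright on ADM (9.54) and duct (9.07). It may belong with the 27, and without it only members of the enzyme list are left as controls. Probes of a gene can also differ in affinity and in the transcript forms they bind. The prediction for abundant RNA of the named genes, written beforehand, was a median gap within 1 log2 unit. For the 27 genes as a set, the median of 12.5 and the smallest gap of 7.97 argue against it. These gaps do not show what the bright probes bind, so probe-specific signal from something else stays undecided. Genes with 1 probe were not covered. No biological explanation was tested. The differences of the 43 genes between arrays were uniform, with a median of −0.58 (SD 0.141) in ADM minus acinar and −1.11 (SD 0.205) in duct minus acinar.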
